A study of Mus musculus with 26 samples.

How the data were processed

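Gene expression was measured in 26 immortalized clonal mouse adipose cell lines, 23 derived from the inguinal depot and 3 from the interscapular depot, with 1 Affymetrix mouse whole-genome array per clone. Per the labels' protocols, the cells were fully differentiated, exposed for 4 h to forskolin, an activator of adenylyl cyclase, and their total RNA was hybridised as biotinylated cRNA. The sample protocols give the treatment for all 26 clones, while the short description in the experiment file of clone N13 alone adds the letters FSK, so the treatment rests on the protocols. The forskolin dose is 10 micromolar in the series text and 10 millimolar in the sample protocols, and this difference was left unresolved. The depot was taken from the labels. The labels do not say which inguinal clones count as beige and which as white, so inguinal clones were never put into groups.

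The deposited values were 1 linear intensity per probe set and array. How the authors summarised the probes, and whether they scaled the arrays to a common level, is not given in the sources used here. The array medians lay between 40.3 and 45.7 and the array means between 412 and 506 intensity units, and between 393 and 540 values per array were 1 or less. Values were used as log2(intensity + 16) with no further scaling, so differences and folds understate the change of dim genes. Of 45101 probe sets, 64 were controls, 34958 carried 1 gene symbol, 932 carried several and 9211 none in the platform annotation used here, which can be old; a probe set with several symbols or none was left out. Of the probe sets with 1 symbol, 34754 were matched to a RefSeq gene table (GRCm38.p6, used for names only), and 2 symbols were updated. The 18195 named genes were each represented by the probe set with the highest mean. A gene was kept when it lay above the median of its array in at least 3 arrays, which left 12735 genes. No genome build is named by the files, and no coordinates are given.

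Depots were compared with limma 3.58.1 (lmFit and eBayes, R 4.3.3), as the interscapular minus the inguinal mean, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were fixed before the data were examined. Of 33 lists, 31 had at least 5 measured genes and were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. Lists labelled here as brown or beige markers of the study were recalled from work on these same lines and are not independent evidence. Ucp1 was compared by an exact permutation test over the 2600 splits of 26 arrays into 3 and 23. The likeness of the interscapular clones was the mean Pearson correlation of their gene-centred profiles, set against the same 2600 choices of 3 arrays. Among inguinal clones, each gene was regressed on log2 Ucp1 with limma, and list means were correlated with Ucp1 with 100000 permutations. A mixture of 2 components (mclust 6.1.1) did not improve on 1 component for log2 Ucp1, with a difference in BIC of -1.13, so the 23 clones were treated as a continuum. The spread of a list was its median SD among inguinal clones, ranked among 10000 random lists matched on mean level.

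For the members of each list, p-values were also adjusted over the list alone. Named genes were the 12 with the largest difference each way past the threshold, Ucp1, the members of the fixed lists, the 12 with the largest SD and the 12 with the highest and lowest moderated t for Ucp1. Scanner, chip lot and fluidics station, read from the experiment files deposited for each array, served as technical batches. So did scan session, built from the scan dates in these files by joining dates at most a few days apart. A session can therefore span several days. No 2 arrays were copies of each other. The labels pair no clones across depots, and groups of 3 and 23 were not screened for single outlying samples.

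The scripts were tested on simulated data over 12735 genes. Each gene was drawn independently of the others, with normal noise and its inguinal mean and SD in both depots. For the depot comparison, 76% of genes planted with a log2 difference of 1 and 91% of those with 2 were recovered, with 14 false calls. For the relation to Ucp1, 84% of genes with a slope of 0.5 and 97% with a slope of 1 were recovered, with 7 false calls. Correlated genes and unequal SDs were not simulated, so false calls can be more frequent in the real arrays. Splits of the real arrays other than by depot, of which only some were drawn, called up to 198 genes. The alternatives covered scaling between arrays, the rule for probe sets, the pseudocount, the filter, batches, array weights, the degree of differentiation, thresholds and leaving out single clones. Precision is limited by the number of arrays, with only 3 interscapular clones in the depot comparison. Figures were drawn with matplotlib 3.10.9.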

Results

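Clonal lines from the inguinal fat depot (n = 23), which holds white and beige fat cells, and from the interscapular depot (n = 3), which holds brown fat cells, were profiled after differentiation and, per the labels' protocols, 4 h of forskolin. The treatment of each clone rests on those protocols and was not checked otherwise. Each clone was measured on 1 array, so p-values describe the spread among these clones and not repeated cultures of a clone. Scan session 1 held 17 inguinal and 2 interscapular arrays, scan session 2 held 3 and 1, and the remaining 3 inguinal arrays were scanned in sessions 3 and 4. Scanner 1 read 12 inguinal and 1 interscapular arrays, and scanner 2 read 11 and 2. Chip lot 2 held 4 inguinal and 2 interscapular arrays, and chip lot 4 held 3 and 1. Most inguinal arrays were of chip lots with no interscapular array. Of the interscapular clones, BAT1 and BAT6 were on fluidics station 7 and BAT8 on station 1, and most inguinal arrays were on other stations.

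Hoxc10, Fgf21, Car9 and Plac8 were among the genes that differed most between the depots. Hoxc10, a homeobox gene of the posterior trunk and limb, stood at 10.04 ± 0.32 (log2, SD, n = 23) in inguinal clones and lay below the array median in all 3 interscapular clones (4.41 ± 0.05, limma adjusted p = 2.37e-19). Fgf21, a secreted metabolic hormone, was 4.88 log2 units higher in interscapular clones (adjusted p = 1.34e-09), and Car9, a carbonic anhydrase induced by hypoxia, was 4.84 higher (10.02 ± 0.19 against 5.18 ± 0.21). Car9 lay below the array median in all 23 inguinal clones, and Fgf21 in 17 of them, so the size of these differences is set against background signal and is approximate. Plac8 was uniform among inguinal clones at 14.11 ± 0.12 and fell to 9.82 ± 0.60 in interscapular clones.

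The other genes with the largest differences were Rgcc (5.35 higher), Depp1 (4.74), Plp2 (4.24), Hoxb5os (3.58), the brown preadipocyte transcription factor Ebf2 (3.41), Lmcd1 (3.16), Serpinb9g (3.08), Nptx1 (3.07) and Trarg1 (3.02), a regulator of glucose transporter trafficking. Depp1 lay below the array median in 20 and Ebf2 in 17 of the 23 inguinal clones. Rps4l was 4.74 higher, but its probes may also take transcripts of its near copy Rps4x. Lower genes included the matrix gene Efemp1 (-5.60), the eosinophil chemokine Ccl11 (-4.97), the glutathione transferase Gsta4 (-4.41), Ramp3 (-4.26), the peptide hormone Cck (-3.99), Prr9 (-3.93), the growth factor Ptn (-3.90), the retinoic acid binding protein Crabp1 (-3.79), Glipr1 (-3.70) and the cytokine receptor subunit Csf2rb (-3.53). A dimmer probe set of Nptx1 gave 0.57, of Glipr1 -0.75 and of Csf2rb -1.84. Those of Ptn gave -4.21 and -0.01 and those of Ebf2 3.23 and 1.87. The dimmer probe sets of Rgcc (5.50) and Depp1 (4.69) stayed close to the values above. Csf2rb lay below the array median in all 3 interscapular clones, and Efemp1, Prr9 and Crabp1 in 2 of them, so the size of these falls is approximate. Of the 24 genes with the largest differences, 20 passed without each interscapular clone in turn, and the exceptions were Lmcd1, Serpinb9g, Crabp1 and Csf2rb. Cck passed there, but its difference was -0.24 within session 2 (adjusted p = 0.932) and -3.03 within scanner 2 (adjusted p = 0.129), and it ranged from -5.56 to -0.24 over the alternatives.

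In all, 1299 of 12735 genes passed (limma), 580 higher and 719 lower in interscapular clones, and 504 of them differed by at least 1 log2 unit. In 365 genes (2.87%) the depots did not overlap, against 0.0769% by chance. The count was 1403 with scan session as a block, 1280 with scanner, 983 with chip lot and 622 with fluidics station, and within batches it was 550 in session 1, 208 in session 2, 101 on scanner 1, 644 on scanner 2 and 99 in chip lot 2. It was 440 without clone BAT6 (424 of them among the 1299), 738 without BAT8, 883 without BAT1 and 689 with the general adipocyte list as a covariate.

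Hox genes moved both ways. Of 23 measured, 7 were higher and 8 lower in interscapular clones, 8 and 8 when adjusted over the list alone. In the Hoxc cluster 5 of 7 genes fell, namely Hoxc6 (-2.80), Hoxc8 (-3.20), Hoxc9 (-2.76), Hoxc10 (-5.62) and Hoxc13 (-1.39), while Hoxc4 (-0.26) and Hoxc5 (-0.39) did not pass. In the Hoxa cluster the anterior genes Hoxa2 (0.88), Hoxa3 (0.94), Hoxa4 (0.84) and Hoxa5 (1.13) rose, as did Hoxa11 (0.73), and Hoxa7 (-1.23), Hoxa9 (-2.83) and Hoxa10 (-1.56) fell. Hoxb5 (2.01) and Hoxb6 (0.79) rose, and neither measured Hoxd gene passed. The inguinal means of Hoxa2 (5.22), Hoxa4 (5.42) and Hoxb5 (5.69) lay below the lowest array median. So did the interscapular means of Hoxa7 (5.40), Hoxa9 (5.02), Hoxa10 (4.71), Hoxc9 (5.62), Hoxc10 (4.41) and Hoxc13 (5.01). The sizes of these differences are therefore approximate. As a list, Hox genes did not pass against other genes (camera adjusted p = 0.136), while their mean was 6.97 ± 0.05 (SD, n = 3) in interscapular against 7.60 ± 0.19 (n = 23) in inguinal clones (exact permutation adjusted p = 0.00397, a test chosen after the data were seen), and fry's test for change in either direction gave an adjusted p of 7.76e-22. Of 29 limb and trunk patterning genes, Hand2 (-1.46), Emx2 (-1.14) and Tbx3 (-1.0) fell and Foxc1 (1.0) rose, with camera adjusted p = 0.158; within scanner 1 the difference of Tbx3 was 0.09. Without each interscapular clone in turn, 10 of the 15 Hox genes passed, all but Hoxa3, Hoxa4, Hoxa5, Hoxb6 and Hoxc13, and 0 of the 4 patterning genes (limma, all 4 with all arrays).

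**Figure D1:**
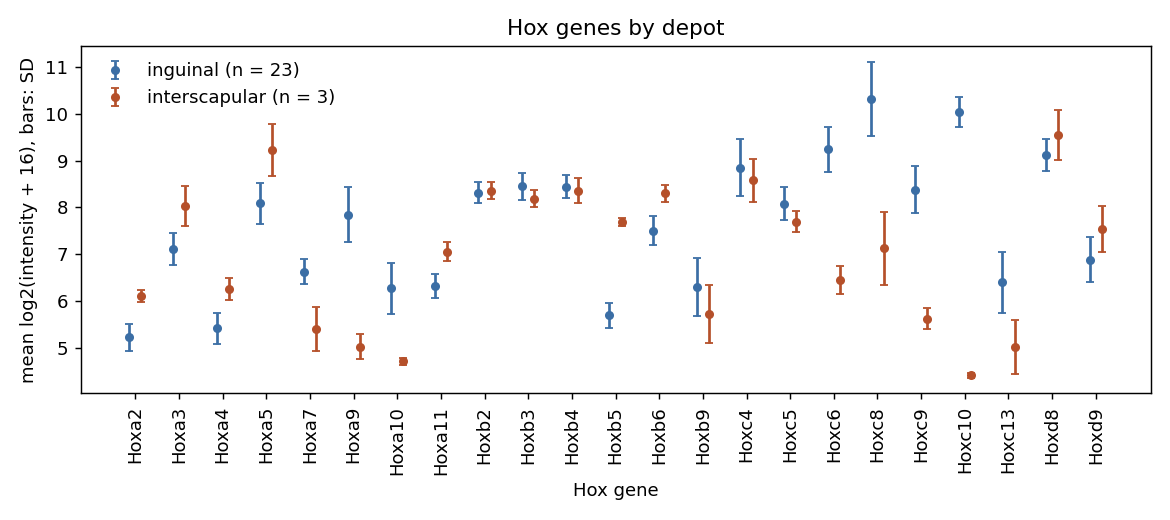
Mean log2(intensity + 16) of the 23 measured Hox genes in inguinal (blue, n = 23) and interscapular (orange, n = 3) clones, with SD as bars. Hoxc6 to Hoxc13 and Hoxa7 to Hoxa10 lie lower in interscapular clones, and Hoxa2 to Hoxa5 and Hoxb5 lie higher.

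By camera over all arrays, thermogenic and fatty acid oxidation genes were higher in interscapular clones as lists, though few members passed singly. By exact permutation of the list mean, chosen after the data were seen, the thermogenic list passed (adjusted p = 0.00397). Its mean difference was 1.05 against a median of 0.65, so genes such as Fgf21 (4.88) and Ebf2 (3.41) weighed on the mean. The list was not tested without them. The fatty acid oxidation (adjusted p = 0.068) and general adipocyte lists (adjusted p = 0.117) did not pass by that permutation. Of 22 thermogenic genes, 4 rose, Fgf21, Ebf2, Acot2 (1.71) and the muscle-type cytochrome oxidase subunit Cox7a1 (1.80), 18 did not pass and 10 rose when adjusted over the list alone (camera adjusted p = 4.57e-06; adjusted p = 0.066 with an estimated correlation). Of 24 fatty acid oxidation genes, 5 rose, Hadhb (0.83), Etfa (0.92), Acaa2 (0.96), Crat (0.98) and Cpt2 (0.79), and 9 over the list alone (camera adjusted p = 1.80e-05; adjusted p = 0.513 with an estimated correlation). General adipocyte genes had 2 of 24 rising, Klb (2.86) and Insr (1.0), and 4 over the list alone, with a median of 1.02 (adjusted p = 1.46e-05; adjusted p = 0.594 with an estimated correlation).

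Few members also passed singly in the following lists, which shifted upward by camera. By exact permutation of the list mean, the brown lineage (adjusted p = 0.00715) and unfolded protein response lists (adjusted p = 0.0187) passed. The TCA cycle (adjusted p = 0.0845), oxidative phosphorylation (0.317), lipogenic (0.151) and hypoxia lists (0.139) did not pass by that permutation. Idh3b (0.59) was the only riser of 16 TCA cycle genes (adjusted p = 0.000528; adjusted p = 0.513 with an estimated correlation). Cox4i1 (0.45) and Uqcrh (0.59) rose among 62 oxidative phosphorylation genes (adjusted p = 0.00533; adjusted p = 0.711 with an estimated correlation). None of either list passed over the list alone. Acacb (1.13) and Lpin1 (1.19) rose among 19 lipogenic genes (adjusted p = 0.0228; adjusted p = 0.693 with an estimated correlation), with 2 over the list alone. Atf3 (2.33), Herpud1 (0.71) and Edem1 (0.68) rose among 18 unfolded protein response genes, with 4 over the list alone (adjusted p = 0.0167; adjusted p = 0.477 with an estimated correlation). Car9 was the 1 riser of 17 hypoxia genes, also over the list alone (adjusted p = 0.0167; adjusted p = 0.693 with an estimated correlation). Of 7 brown lineage genes only Ebf2 rose, and 4 over the list alone (adjusted p = 0.00325; adjusted p = 0.108 with an estimated correlation). The oxidative phosphorylation median of 0.15 turned to -0.01 without BAT1 (adjusted p = 0.802) and to -0.23 within scanner 1, where BAT8 was the 1 interscapular clone and the list passed in the opposite direction (adjusted p = 2.04e-05). On that scanner 5 lists passed upward and 6 downward, against 10 and 4 over all arrays, and the fatty acid oxidation list did not pass (adjusted p = 0.792). The fatty acid oxidation median of 0.54 was 0.43 within session 1, 0.55 within session 2, 0.13 within scanner 1 and 0.72 within scanner 2. Left without 1 interscapular clone at a time, 3 of the 4 thermogenic calls (Fgf21, Ebf2 and Acot2), 1 of the 2 adipocyte calls (Klb) and 0 of the 5 fatty acid oxidation calls held each time (limma). Of the other calls, Ebf2 and Car9 held each time, and none did among TCA cycle (1), oxidative phosphorylation (2), lipogenic (2) and unfolded protein response genes (3), and Idh3b, Acacb, Lpin1 and Atf3 did not pass without any 1 of the 3 clones. Over all alternatives Uqcrh lost its call in 31 of 47, Cox7a1 in 27 of 47 and Acacb in 19 of 46. Without BAT1 the TCA cycle (adjusted p = 0.0635) and lipogenic lists (adjusted p = 0.609) did not pass.

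Markers recalled from the study moved by depot, which is not independent evidence. Of 5 measured brown markers, 4 rose, Pdk4 (2.72), Hspb7 (2.41), Ebf3 (2.35) and Fbxo31 (1.5), and all 5 over the list alone (camera adjusted p = 8.24e-07; 0.00156 as the adjusted p with an estimated correlation). Of 8 beige markers, Tmem26 (-2.78), Klhl13 (-2.39), Tbx1 (-2.11), Sp100 (-1.68) and Cd40 (-1.36) fell and 3 did not pass, with 5 over the list alone (adjusted p = 0.000243; adjusted p = 0.0644 with an estimated correlation). All 4 brown and 3 of the 5 beige calls (Tmem26, Klhl13 and Sp100) held without each interscapular clone in turn.

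Interferon response genes were lower in interscapular clones, unevenly. Of 30 measured, 13 fell and 20 over the list alone, among them Trim25 (-2.69), Ifit3 (-2.12), Oasl2 (-1.86) and Bst2 (-1.70) (camera adjusted p = 8.40e-12; adjusted p = 0.308 with an estimated correlation). The list mean was 9.76 ± 0.35 (SD, n = 23) in inguinal clones, and 9.88 in BAT1, 8.76 in BAT8 and 7.38 in BAT6. Sp100 is also among the beige markers. Without BAT6 only 2 of the 13 genes passed, Trim25 and Sp100, against 7 without BAT8 and 13 without BAT1. The median difference of -1.10 became -0.35 without BAT6 and -1.71 without BAT1, and it was -0.33 within session 1, -2.45 within session 2, -0.83 within scanner 1 and -1.23 within scanner 2. BAT6 had the highest log2 ratio of 3' to 5' actin signal, an RNA quality measure, of all arrays (1.15, against at most 0.99 in inguinal clones).

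Proliferation and fibroblast genes were also lower by camera. By exact permutation of the list mean neither list passed (adjusted p = 0.139 for cell cycle, 0.0609 for preadipocyte and fibroblast genes). By fry the second passed (adjusted p = 0.023) and the first did not (adjusted p = 0.143). Both tests were chosen after the data were seen. In the cell cycle mean, inguinal clones D16 (6.51) and M4 (6.70) lay below all 3 interscapular clones (6.82 to 6.98). Rrm2 (-1.57), Mcm5 (-1.42) and E2f1 (-0.88) fell among 34 cell cycle genes, with 3 over the list alone (adjusted p = 0.000118; adjusted p = 0.693 with an estimated correlation). Thy1 (-2.38), Sfrp1 (-1.82) and S100a4 (-1.13) fell among 18 preadipocyte and fibroblast genes, with 1 higher and 5 lower over the list alone (adjusted p = 0.0228; adjusted p = 0.513 with an estimated correlation). The cell cycle median of -0.63 was -0.84 within session 1, -0.12 within session 2, -0.65 within scanner 1 and -0.62 within scanner 2, and the list no longer passed within session 2 (adjusted p = 0.645) or with chip lot as a block (adjusted p = 0.0804). The preadipocyte and fibroblast list did not pass without BAT8 (adjusted p = 0.13), and of the single genes Rrm2 and Thy1 passed without each interscapular clone in turn. Mcm5 lost its call in 21 of 47 alternatives.

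**Figure D2:**
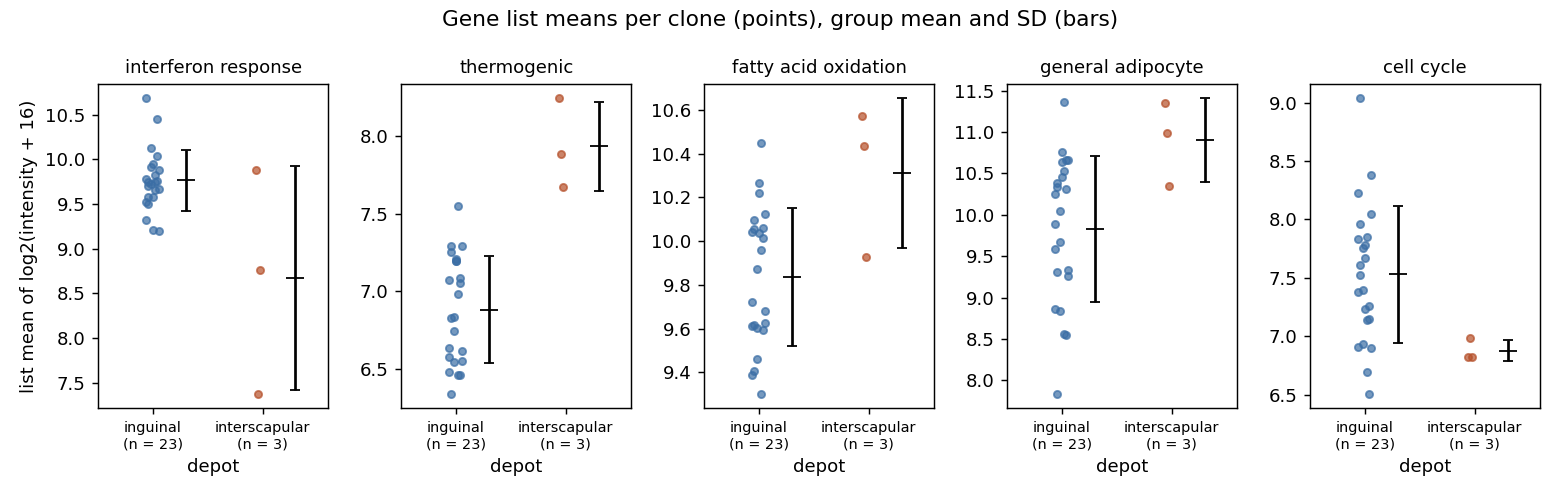
List means of log2(intensity + 16) per clone (points) by depot for 5 gene lists, with group mean and SD as bars (inguinal n = 23, interscapular n = 3). The interscapular clones lie above every inguinal clone in the thermogenic mean, at the closest 7.67 in BAT8 against 7.55 in D12. Genes with large differences such as Fgf21 and Ebf2 weigh on that mean. For the interferon list the interscapular clones spread from 7.38 to 9.88.

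Among markers of other cell types, the mean of 11 macrophage and leukocyte genes was 7.17 ± 0.14 (SD, n = 3) in interscapular against 6.79 ± 0.20 (n = 23) in inguinal clones. It was higher by exact permutation (adjusted p = 0.0187) and by fry (adjusted p = 0.023), both chosen after the data were seen, and did not pass by camera (adjusted p = 0.0746). Cd68 (2.12) was the 1 riser of the list, with 2 over the list alone, and did not pass without BAT8. Smooth muscle (camera adjusted p = 0.641, exact permutation adjusted p = 0.271, 0 of 10 genes by limma), skeletal muscle (0.975 and 0.811, 0 of 10) and Schwann and neural genes (0.643 and 0.174) did not pass as lists, and in the last S100b rose by 1.12 and Tubb3 fell by 0.86, 2 of 7, of which neither held without each interscapular clone in turn. Fewer than 5 endothelial and fewer than 5 sex-linked genes were measured, too few for a test. Of 13 adrenergic signalling genes, the protein kinase A subunit Prkar1b (-3.03) and the adenylyl cyclase Adcy6 (-0.62) fell (adjusted p = 0.581), and only Prkar1b passed without each interscapular clone in turn. Of 24 genes of the response to cAMP, which forskolin raises, only Atf3 rose (adjusted p = 0.503), and it did not pass without any 1 of the interscapular clones.

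Ucp1, the uncoupling protein that defines thermogenic fat, was low and did not separate the depots. It averaged 6.53 ± 0.43 (log2, SD, n = 3) in interscapular and 5.89 ± 0.81 (SD, n = 23) in inguinal clones, a difference of 0.64 (exact permutation test, two-sided, p = 0.205). Inguinal clones ranged from 9.24 to 170.82 intensity units. Ucp1 lay above the array median in 9 of 23 inguinal and 3 of 3 interscapular clones, and 3 inguinal clones exceeded the highest interscapular clone. The difference was 0.76 within session 1, -0.04 within session 2, 0.39 within scanner 1 and 0.71 within scanner 2. It was 0.39 without BAT1, 0.71 without BAT6 and 0.80 without BAT8.

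Across all genes the interscapular clones resembled each other. Their mean correlation of centred profiles was 0.499, the highest of all 2600 choices of 3 arrays (exact permutation, one-sided, p = 0.000385, the smallest these choices allow), and the highest among inguinal clones alone was 0.438. Each interscapular clone had another interscapular clone as its nearest neighbour. BAT1 and BAT6 shared scanner 2 and fluidics station 7, and BAT1 and BAT8 shared chip lot 2. Shared batches were not tested as a source of this likeness. Nor was a common origin of these clones, on which the labels used here give only the depot.

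Among inguinal clones, the closest followers of Ucp1 were Mccc1, an enzyme of leucine breakdown, with a slope of 0.90 ± 0.13 (log2 per log2 Ucp1, SE, n = 23, r = 0.827), 9630013D21Rik (0.75), the medium-chain acyl-CoA dehydrogenase Acadm (0.74 ± 0.11), Ubd (0.93), Gpat3 (0.93), Orm1 (1.41), Crat (0.49), Lgals12 (1.06), the lipid droplet protein Cidec (1.39), the triglyceride synthase Dgat1 (0.64), the lipogenic transcription factor Mlxipl (0.92) and Retsat (0.48). Falling genes included Ada (-0.36), Ntn1 (-0.62), Cck (-1.03), Selenon (-0.34) and Hoxb4 (-0.23).

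In total 188 of 12734 genes passed (limma), 174 rising and 14 falling, and 13 of the risers were general adipocyte genes such as Adipoq (0.94), Pparg (0.81) and Plin4 (1.11). With the general adipocyte list as a covariate no gene passed, and 432 had an unadjusted p under 0.05 (limma). Within batches 4 genes passed in session 1, 202 on scanner 1 and 0 on scanner 2 (440 unadjusted), and with batch as a block 39 passed for session, 134 for scanner, 37 for chip lot and 0 for fluidics station (870 unadjusted). The count rested on single clones, being 19 without D12, 66 without E3, 69 without G10, 94 without I2, 101 without F4, 105 without N13, 121 without E1, 122 without G12 and 125 without X3.

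Of 31 list means, 7 correlated with Ucp1 among the 23 inguinal clones by Pearson, all positively. By Spearman 9 passed, these 7, the beige markers of the study and, falling, the Hox list (rho = -0.508, permutation p = 0.0141, adjusted p = 0.0486; r = -0.367, permutation p = 0.0854, adjusted p = 0.165). Thermogenic genes without Ucp1 gave r = 0.752 (permutation p = 4.0e-05, adjusted p = 0.00108; rho = 0.756, permutation p = 9.0e-05), with 4 of 21 members rising, among them the cAMP-induced coactivator Ppargc1a (1.05), and 10 over the list alone. Fatty acid oxidation gave r = 0.735 (permutation p = 7.0e-05, adjusted p = 0.00108; rho = 0.788, permutation p = 2.0e-05), with 7 of 24 rising and 18 over the list alone. General adipocyte genes gave r = 0.704 (permutation p = 0.00021, adjusted p = 0.0013; rho = 0.722, permutation p = 0.00021), with 13 of 24 rising and 22 over the list alone. The TCA cycle list gave r = 0.713 (permutation p = 0.00013; rho = 0.732, permutation p = 0.00014), lipogenesis 0.704 (p = 0.00017; rho = 0.724, p = 0.00016), oxidative phosphorylation 0.594 (p = 0.00219; rho = 0.547, p = 0.0074) and white fat genes 0.535 (p = 0.00822; rho = 0.531, p = 0.0105), all by permutation and all passing after adjustment. Without D12 and X9, the clones farthest from the Ucp1 median, r was 0.667 for thermogenic, 0.672 for fatty acid oxidation and 0.653 for general adipocyte genes, while oxidative phosphorylation (0.450) and white fat genes (0.487) did not pass (adjusted p = 0.118 and 0.11).

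For the thermogenic list r was 0.724 within session 1, 0.878 on scanner 1 and 0.532 on scanner 2, for fatty acid oxidation 0.709, 0.809 and 0.599, for the general adipocyte list 0.643, 0.885 and 0.382, and for the white fat list 0.505, 0.859 and 0.0988. With scan session as a block 6 lists passed, and 7 with scanner, with fluidics station and with chip lot, in the last case 6 rising and 1 falling. No list passed on scanner 2 alone (n = 11, lowest permutation adjusted p = 0.501) or given the mean of the general adipocyte list (lowest adjusted p = 0.818), where r was 0.376 for thermogenic and 0.349 for fatty acid oxidation genes. The beige markers of the study gave r = 0.407 (permutation p = 0.0512, adjusted p = 0.113; rho = 0.531, permutation p = 0.0101, adjusted p = 0.0408), and the brown markers 0.273 (permutation p = 0.207, adjusted p = 0.281).

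**Figure D3:**
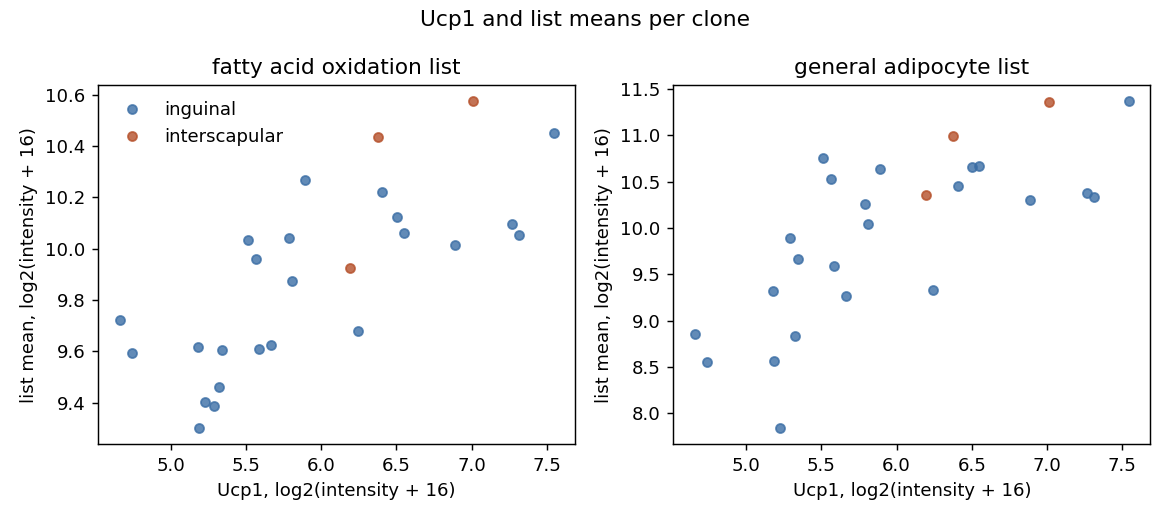
Mean of the fatty acid oxidation list and of the general adipocyte list against log2(intensity + 16) of Ucp1, each point 1 clone (inguinal blue, interscapular orange). Both lists rise with Ucp1 among inguinal clones, with r = 0.735 and r = 0.704.

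Inguinal clones differed most from each other in Ccl6, Cyp2e1 and Car3. The largest SDs were those of the chemokine Ccl6 (2.00), Cyp2e1 (1.97), the carbonic anhydrase Car3 (1.97), S100a8 (1.88), Lrg1 (1.88), the lipogenic regulator Thrsp (1.83), Mup3 (1.82), the LIM homeobox gene Isl1 (1.81), angiotensinogen Agt (1.79), Chl1 (1.79), the adipokine Retn (1.78) and haptoglobin Hp (1.76). D12 was the highest clone for Cyp2e1, Car3, Lrg1, Thrsp, Chl1 and Retn, while I2 was the lowest for Ccl6, S100a8, Lrg1, Thrsp, Agt, Chl1 and Retn. The median SD over all genes was 0.32, and 244 genes (1.92%) exceeded 1. Of 31 lists, 22 varied more than the 95th percentile of matched random lists, with general adipocyte genes at a median SD of 1.01, whereas oxidative phosphorylation genes (0.25) stood at the percentile 0.34.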

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

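The leave-one-out ranges of the ratios below, the count of clones below the second-highest interscapular clone, the test of probe sets with no gene symbol, and the scan session block and the session 2 values for interferon genes were chosen after the results were seen, and chip lot was picked once the batches were known. Probe sets with no gene symbol, left out of the gene comparison, also differed between the depots: 123 of 3350 tested passed (limma), 73 higher and 50 lower in interscapular clones. That is 3.67% of them, against 10.2% of named genes, and no explanation was tested. The real split of the 26 arrays into 3 and 23 was set among 100 splits, the others drawn from the 2600. Only the real one (1 of 100) called as many genes, 1299 against at most 198 in the others drawn. This argues against chance for the gene count, at no finer level than 1 in 100. Most drawn splits left all interscapular arrays among the 23, where depot differences widen the spread and can lower the count. For the gene lists, 5 of 100 splits gave as many as the 14 of the depots, with up to 17 in another split, so chance was not excluded for the number of lists. Camera at its preset correlation called a median of 7 lists in the other splits. A call by that test alone is therefore weak evidence for a single list, and its small adjusted p-values overstate it.

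The Hoxc genes fell in the interscapular clones. In each leave-one-out range here and below, the ratio was taken to the median difference without the same clone. A difference between scan sessions as the whole source was argued against, since within session 1 the median difference was 0.960 of that over all arrays (0.958 to 0.998 when 1 interscapular clone was left out), and all interscapular clones (at most 6.74 in the Hoxc mean) lay below all inguinal clones (at least 8.20). So was a difference in differentiation, since the general adipocyte list as a covariate left 0.899 of it (0.838 to 0.925). A difference in depot of origin may stand behind the pattern, which stays a hypothesis: with chip lot as a block Hoxc6, Hoxc8, Hoxc9 and Hoxc10 passed and Hoxc13 did not, and culture history was not tested.

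Interferon response genes were lower in the interscapular clones, but not in all. The bound set beforehand for a difference that rests on the choice of inguinal clones, at least 5 of them below the highest interscapular clone, was met with 17 of 23. By that bound the explanation is not excluded. That bound could not tell overlap caused by inguinal clones from overlap caused by 1 interscapular clone within their range: BAT1 stood at 9.88, and 0 inguinal clones lay below BAT8, the next interscapular clone, a count chosen after the first was seen. The lowest inguinal clone stood at 9.20, above BAT8 (8.76) and BAT6 (7.38), which argues against that explanation for BAT8 and BAT6. Within session 1 the median difference was 0.30 of that over all arrays (-0.250 to 0.947 without 1 clone), below the bound set beforehand for scan session. That comparison leaves out BAT6, the lowest clone, which was scanned in session 2, so it could not part the session from the clone. Scan session as the whole source was argued against by other values. With session as a block 0.894 of the median difference stayed, and the 3 inguinal clones of session 2 stood at 9.76 to 10.03, against 7.38 in BAT6. With 1 interscapular clone left out, the block kept 0.887 to 0.962 of the median difference without that clone. Without BAT6 that difference was itself much smaller, so this range does not say that the difference held without BAT6. Differentiation was argued against too, since as a covariate it left 0.933 (0.816 to 0.929 in the leave-outs, taken in the same way). The origin of the spread among 3 clones stays open, and a fault of a single array was not tested.

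Fatty acid oxidation genes were higher in the interscapular clones by camera, but not by exact permutation of the list mean (adjusted p = 0.068). The general adipocyte list as a covariate left 0.396 of the median difference (0.385 to 0.457), below the bound set beforehand, so a higher degree of differentiation of the interscapular clones is a candidate explanation. The actin ratio as a covariate left 0.951 (0.811 to 0.989), which argues against RNA quality. Depot and differentiation could both contribute, and the covariate can also take away a part that belongs to the depot.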

How the results depend on the processing

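The exact permutation of list means, fry's test of a shift one way and the fits without scan sessions 3 and 4 were chosen after seeing the data, and chip lot and fluidics station were picked from the planned batches once the batches were known. On scanner 1 and in session 2, 1 interscapular clone was left and is assumed to vary like the inguinal ones. The count of depot genes, 1299, was 542 at an adjusted p under 0.01, 504 with a log2 difference of at least 1, 689 with the adipocyte covariate, 622 with the fluidics station block, and 550 in session 1, 208 in session 2, 101 on scanner 1, 644 on scanner 2 and 99 in chip lot 2; without single clones they ranged from 440 to 1551. The count of depot lists, 14, was 9 with chip lot, 9 with fluidics station, 6 with the adipocyte covariate, 1 with an estimated correlation and 8 by exact permutation, which held 6 of the 14 and the Hox and macrophage lists, and ranged from 11 to 16 without 1 interscapular clone. The count of genes following Ucp1, 188, was 123 with pseudocount 64, 39 with scan session, 37 with chip lot, 4 within session 1, 53 without sessions 3 and 4, and 0 on scanner 2, with fluidics station and with the adipocyte covariate (limma, 440, 870 and 432 unadjusted); without single inguinal clones they ranged from 19 to 266. Without sessions 3 and 4 the depot counts were 1670 genes and 12 lists, and 6 lists followed Ucp1. The count of lists following Ucp1, 7, was 0 on scanner 2 and with the adipocyte covariate. Directions turned for Ucp1 between depots in session 2 (-0.040) and with the adipocyte covariate (-0.058), for Tbx3 on scanner 1 (0.094) and for the correlation of the white fat list with that covariate (-0.126). By camera's direction, depot lists turned for oxidative phosphorylation on scanner 1 (median -0.23, where it passed downward) and without BAT1 (-0.0069, range -0.0069 to 0.35 without 1 interscapular clone), and with the adipocyte covariate for the lipogenic list (-0.046) and for the adipocyte list, which is the covariate (0.0057, a median still above 0). The median alone changed sign for the lipogenic list in session 2 (-0.056) and on scanner 1 (-0.054), the hypoxia list in session 2 (-0.041) and with the covariate (-5.9e-05), and the preadipocyte list in chip lot 2 (0.043), none of which passed there. The likeness of the interscapular clones (0.461 to 0.588 without 1 of them) and the spread among inguinal clones (19 to 23 lists) kept their calls under the alternatives run. Those alternatives held no batch for either result. Of 5010 alternatives of single log2 differences 4402 kept direction and call and 605 lost the call, and of 955 slopes on Ucp1 680 and 275. Apart from Ucp1, only genes already called were counted, and many alternatives left out 1 inguinal clone. A high kept share of the log2 differences was thus partly built in. Dim genes are limited by background signal.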

Other observations

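The checks within chip lot, by fluidics station and without clone E1 were chosen after the result was seen. Matrix genes moved both ways between the depots: of 38, Col4a1 (1.71) and Col4a2 (1.46), chains of basement membrane collagen, Col5a3 (1.79) and Mgp (2.56) rose in interscapular clones, and Fmod (-3.40), Mmp3 (-3.35), Postn (-1.55) and Thbs2 (-1.12) fell, with 4 higher and 4 lower over the list alone (camera adjusted p = 0.641). Only Fmod and Mmp3 passed without each interscapular clone in turn. Of 27 secreted factors, Fgf21 and Bmp4 (0.65) rose and Ccl2 (-1.76), Ccl7 (-1.64) and Fst (-1.46) fell, with 3 higher and 4 lower over the list alone (adjusted p = 0.999), and Fgf21 and Ccl2 passed without each interscapular clone in turn.

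Of 13 white fat genes, Hoxc8, Hoxc9 and Nnmt (-0.77) fell (adjusted p = 0.434), and of 16 glycolytic genes Aldoc (2.51) rose (adjusted p = 0.0866). Among 13 antigen presentation genes H2-Ab1 (1.88) rose and Psmb8 (-1.09) fell (adjusted p = 0.975). Without each interscapular clone in turn Hoxc8, Hoxc9 and Aldoc passed and Nnmt, H2-Ab1 and Psmb8 did not. No single gene passed (limma) among the cholesterol synthesis (adjusted p = 0.0665), imprinted (0.641), futile cycle (0.789) and p53 target (0.924) lists.

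Inguinal clones whose names share a letter resembled each other: 17 such pairs had a mean correlation of centred profiles of 0.175, against -0.0325 for 236 pairs of different letters (permutation p = 8e-05). A candidate explanation is a common origin of the clones with 1 letter; the labels used here do not say what the letters stand for. Within a scan session the means were 0.222 and -0.0236, and within a chip lot 0.263 and 0.0225 (permutation p = 0.00027). Without E1 the mean was 0.136 (permutation p = 0.00117). Fluidics station partly followed the letters, and pairs on 1 station and on different stations were weighed apart only once both p-values had been seen. The 7 pairs of 1 letter on the same station had a mean of 0.260, against 0.0252 for 27 pairs of different letters (letters permuted within stations, p = 0.0524), so for these the letter and the station cannot be told apart with so few pairs. The 10 pairs of 1 letter on different stations had a mean of 0.116, against -0.040 for 209 (permutation p = 0.00282), which argues against the station as the whole source. If clones of 1 letter are related, the 23 inguinal clones are not fully independent, and the p-values over them would be too small. The same would hold for the depot p-values if the interscapular clones are related to each other, which was not tested.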
